A study of Mus musculus with 8 samples.

How the data were processed

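Hematopoietic stem cells of 4 elektra and 4 wildtype samples were measured on Affymetrix whole-transcript arrays, 1 array per sample, from total RNA of cells sorted from bone marrow. The sample notes state that bones of 2 mice of a genotype were pooled in each sample, whereas the series text speaks of 4 mice per genotype. The wildtype mice were littermates, but no label pairs a sample with a sample of the other genotype. The array design, the annotation release and the filter behind the features listed are not given in the sources used here.

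Per the submitters' processing notes, the authors made the signals with RMA, which corrects background, normalizes by quantiles and summarizes probes by median polish, in Affymetrix Expression Console 1.4. The deposited workbook holds the log2 signals of the 8 arrays, the authors' mean log2 signal of each genotype and their log2 ratio, elektra minus wildtype. It also holds the authors' linear fold change, in which a value with a minus sign is the reciprocal for a transcript lower in elektra, and the authors' p-value, which is not adjusted. The deposited series table holds RMA log2 signals of 41345 features, 7552 of which the workbook does not list. The tables differ by at most 0.16 log2 for shared features, and each column correlated best with the column of the same genotype and replicate number. The workbook values were used.

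The workbook has 33793 features, of which 32074 carry 1 gene symbol, 1591 none and 128 several. Of the first, 27802 were found as a symbol or synonym in the RefSeq gene table of assembly GRCm38.p6, which was used only for current symbols and for the order of neighbouring genes, so no coordinates are given. Tested were features with 1 symbol and a mean over the 8 arrays at or above the median of the feature means, 6.17 log2, with the feature of highest mean kept for each symbol, which left 15710 genes. The groups, tests, gene lists, rule for naming genes and most alternatives were fixed before the data were examined.

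Genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, as elektra minus wildtype without covariates. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Of 29 gene lists, 28 were tested with limma camera at a preset correlation of 0.01, adjusted over the 28 lists, where 5 or more members were tested. The lists were the Schlafen family, DNA replication and S phase, G2 and mitosis, cell cycle inhibitors and quiescence, stem cell identity, interferon-stimulated genes, p53 targets and DNA damage, apoptosis regulators, endoplasmic reticulum and integrated stress response, aminoacyl-tRNA synthetases, cytosolic ribosomal proteins, ribosome biogenesis and Myc targets, oxidative phosphorylation, glycolysis, cholesterol biosynthesis and uptake, antioxidant defence, inflammatory and NF-kB response, immediate early genes, circadian clock, and markers of multipotent progenitors, megakaryocytes and platelets, erythroid cells, granulocytes, monocytes and macrophages, B cells, T and NK cells, mast cells and basophils, and stromal and endothelial cells. Sex-linked genes, the other list, were only reported. Each list was also tested with camera at an estimated correlation, with limma fry, and with an exact two-sided permutation test of the mean of its members per array over the 70 relabellings of 4 and 4 arrays, for which the smallest p is 0.0286.

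Named genes were the measured Schlafen family, up to 10 genes in each direction of largest change among those past the threshold with groups that do not overlap, completed to 10 by the genes of smallest p with groups that do not overlap, and up to 4 members of smallest p in each list. Predicted or unnamed genes, microRNA and small RNA genes, pseudogenes and receptor genes of smell and taste were left out of the part on largest changes, but not of counts. This rule gave 124 genes. Some of them are not reported here. Exceptions named after their values were seen are the called features Gm24564 and Gm20485, the Xlr paralogs, Mn1, and the genes of the imprinted loci, progenitor and heat shock genes and MHC class II genes used in the closing part.

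The procedure was tested on simulated data with arrays and spread like these, in which 200 genes changed. At 1.5-fold 33 of 67 genes, or 49.3%, were called, at 2-fold 60 of 67, or 89.6%, and at 3-fold 63 of 66, or 95.5%, with 9 false calls. With no gene changed limma passed 0, with 791 at an unadjusted p of 0.05. A list shifted by 0.2 log2 was recovered at 0.20, and 0 unshifted lists were called. The simulated noise was independent between genes. The simulation therefore cannot show how often lists of correlated genes are called falsely.

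Alternatives were no filter and a stricter filter on the level (at the upper quartile), quantile normalization, centring of arrays on their medians, eBayes with trend and robust, array weights, the mean of all features of a gene, replicate number as a block, each array left out, the values of the series table, an adjusted threshold of 0.1, and a minimum fold change of 1.5. Chosen after the data were seen were Xist level as a block, the 6 arrays with high Xist, the interquartile range of each array as a covariate, and the deposited p-values. All 35 splits of the 8 arrays into 4 and 4 were run. Single arrays were compared within groups of 4 by Dixon's ratio at its 95% level. Means of further gene sets were compared with 10000 random lists matched on mean level. Features with several symbols or none, and those of the series table alone, were tested apart and stand in the closing part.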

Results

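The transcripts of hematopoietic stem cells from mice homozygous for elektra were compared with those from wildtype littermates. Elektra is a loss-of-function mutation of Slfn2, a Schlafen family gene with known roles in lymphocyte and monocyte quiescence. The cells were sorted from bone marrow by surface markers of long-term stem cells (lineage-negative, Sca-1 and c-Kit positive, CD9 high, CD48 negative, CD150 positive), and the mice had received no treatment. Each genotype had 4 arrays. By the sample notes, each array was prepared from cells pooled from 2 mice, from about 200 pg of RNA and with 12 cycles of PCR. The series text speaks of 4 mice per genotype, so the number of mice behind each array is not settled. Signals were log2 values. The array medians lay between 6.11 and 6.26, and the interquartile ranges between 2.49 and 2.67 in elektra and between 2.41 and 2.64 in wildtype (exact two-sided permutation p = 0.2). Xist, the transcript of the inactive X chromosome, was at 5.06 on elektra replicate 3 and 5.37 on wildtype replicate 3 and between 10.26 and 10.79 on the other 6 arrays, so its level was balanced over the genotypes. Arrays carry no read depth, so the number of arrays limits the precision, and the median standard error of a gene's log2 difference was 0.12.

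The series compares the genotypes to ask how loss of Slfn2 function alters stem cell transcripts at steady state. Plac8, a gene of early progenitors and myeloid cells, and Tjp1, which encodes the tight junction protein ZO-1, were higher in elektra stem cells. So were Ctss, which encodes the lysosomal protease cathepsin S, and the X-linked lymphocyte-regulated gene Xlr4a. The small RNA feature Gm24564 and the predicted gene Gm20485 were lower. These 6 passed the adjusted threshold, but 0 genes passed without elektra replicate 4 or with replicate number as a block. As groups, genes of DNA replication, mitosis, ribosome biogenesis, transfer RNA charging, oxidative phosphorylation and the interferon response lay higher in elektra, while immediate early genes and genes of stem cell identity lay lower. No single gene of these groups passed the adjusted threshold over all genes with limma, and every list call was lost when the correlation among its genes was estimated from the 8 arrays.

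The Slfn2 transcript did not differ between genotypes by more than the spread between arrays. Its mean was 7.99 ± 0.17 (SD, n = 4) in elektra and 7.66 ± 0.52 (SD, n = 4) in wildtype, a log2 difference of 0.33 with a standard error of 0.22 that did not pass (limma adjusted p = 0.598). The elektra arrays read 8.17, 7.90, 7.79 and 8.08 and the wildtype arrays 7.48, 7.22, 7.53 and 8.41. Wildtype replicate 4 set much of this spread, since the difference was 0.58 without it, and it was 0.18 without wildtype replicate 2. None of the other measured Schlafen genes passed either. Slfn9 differed by 0.24, Slfn5 by 0.19, Slfn1 by 0.04 and Slfnl1 by 0.03, all higher in elektra, although Slfn1 turned to -0.03 and Slfnl1 to -0.00091 when elektra replicate 3 or elektra replicate 2, respectively, was left out. Slfn3, Slfn4, Slfn10-ps and Slfn14 lay below the level filter. The Schlafen list of 5 tested genes averaged 0.17 ± 0.08 (SE) and did not pass (limma camera adjusted p = 0.211), with 0 members at an unadjusted p of 0.05. Without the level filter it averaged 0.15 and passed at an adjusted p of 0.04999, the lowest over its settings (highest 0.455).

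Of 15710 genes tested with limma, 6 passed an adjusted p of 0.05, 4 higher and 2 lower in elektra. Plac8 was 2.46-fold higher, at 8.35 ± 0.14 (SD, n = 4) against 7.06 ± 0.22 (SD, n = 4), with a standard error of the log2 difference of 0.12 (limma adjusted p = 0.0114). Xlr4a was 2.41-fold higher, at 9.04 ± 0.39 against 7.77 ± 0.05 (SD, n = 4 each; limma adjusted p = 0.0402). Tjp1 was 1.88-fold higher, at 7.62 ± 0.11 against 6.71 ± 0.09 (SD, n = 4 each; limma adjusted p = 0.0114). Ctss was 1.75-fold higher, at 8.79 ± 0.12 against 7.99 ± 0.11 (SD, n = 4 each; limma adjusted p = 0.0379). All 4 elektra arrays lay above all 4 wildtype arrays for each of these genes. Xlr4a belongs to a family of close paralogs on the X chromosome, and, among paralogs chosen after their values were seen, the log2 difference was 0.85 for Xlr4d-ps and 0.00 for Xlr3a. For Xlr3b, which lay below the level filter and whose genotypes overlapped, at 6.39 ± 0.56 against 5.44 ± 1.18 (SD, n = 4 each), it was 0.95 and fell to 0.42 without wildtype replicate 2. Both lower features fell outside the rule for naming and are named after their values were seen. Gm24564, a small noncoding RNA of the imprinted Meg3 locus, was at 6.68 ± 0.69 against 8.97 ± 0.38 (SD, n = 4 each; log2 difference -2.29, limma adjusted p = 0.0423), and the predicted gene Gm20485 was at 6.14 ± 0.20 against 7.01 ± 0.08 (SD, n = 4 each; log2 difference -0.87, limma adjusted p = 0.0402).

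**Figure D1:**
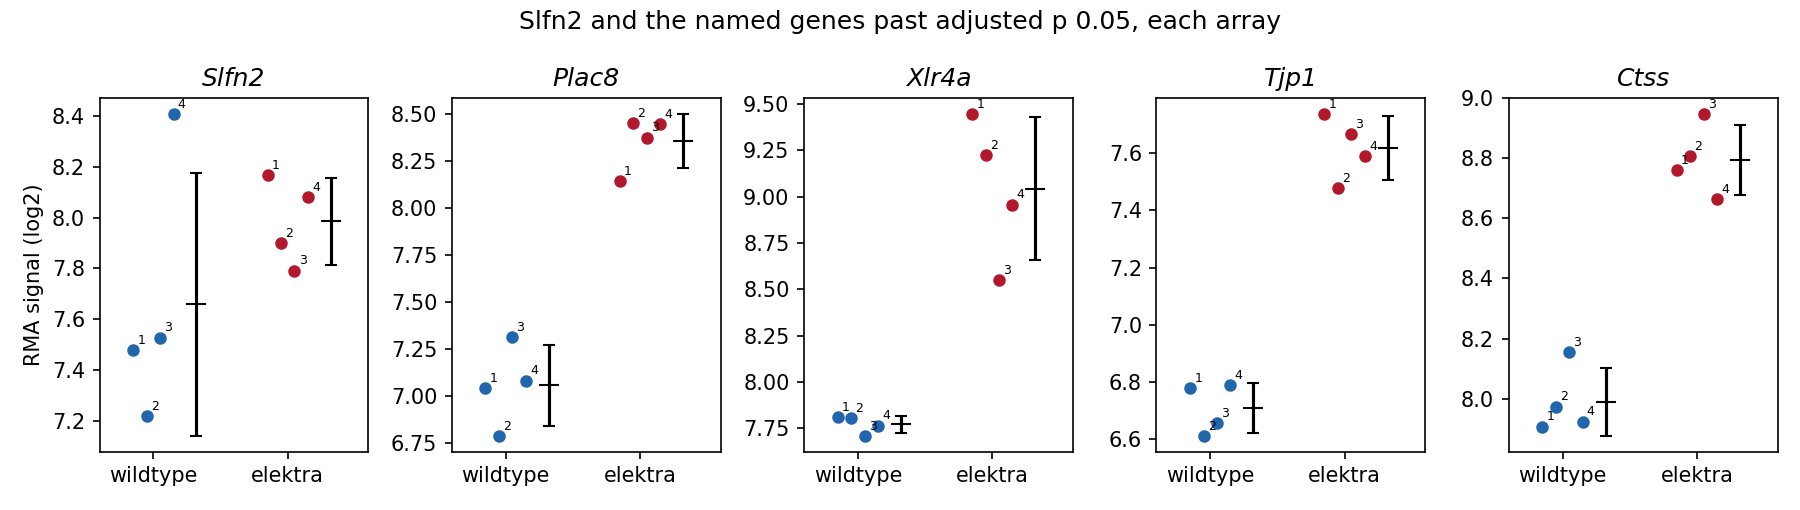
RMA signal (log2, vertical axis) of Slfn2, Plac8, Xlr4a, Tjp1 and Ctss on each array, by genotype (horizontal axis), with points numbered by replicate and bars giving the mean and SD of the 4 arrays. The genotypes overlap for Slfn2, through wildtype replicate 4 at 8.41, and lie apart for the other genes shown.

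These calls depended on single arrays more than their sizes did. The log2 difference stayed between 1.21 and 1.38 for Plac8, 0.87 and 0.96 for Tjp1, 0.75 and 0.87 for Ctss and 1.10 and 1.44 for Xlr4a over all settings, while Plac8 passed in 17 of 20, Tjp1 in 12 of 19, Ctss in 8 of 20 and Xlr4a in 8 of 20. The lower features passed less often, Gm24564 in 7 of 20 settings (-2.54 to -2.02, adjusted p from 0.0226 to 0.232) and Gm20485 in 5 of 19 (-0.93 to -0.79, adjusted p from 0.0212 to 0.191). Gm20485 lost its call without each of the 8 arrays, Gm24564 without each but elektra replicate 2 (0.0302), and both without the level filter or with arrays centred on their medians. The number of genes past the adjusted threshold was 0 without elektra replicate 4, 1 without elektra replicate 1, wildtype replicate 2 or wildtype replicate 3, 2 without wildtype replicate 4, 3 without elektra replicate 2 or elektra replicate 3 and 4 without wildtype replicate 1, and it was 2 without both arrays of low Xist. Plac8 lost its call without elektra replicate 4 (adjusted p = 0.0732, range over its settings 0.00403 to 0.0826), and Tjp1 without elektra replicate 1 (0.0731), elektra replicate 4 (0.0732), wildtype replicate 2 (0.0714) or wildtype replicate 3 (0.0524), in a range of 0.0111 to 0.118. Ctss lost it without each of the 8 arrays, at 0.0524 (wildtype replicate 3) to 0.148 (wildtype replicate 2), and Xlr4a without each array but elektra replicate 3 (0.00889), at 0.0756 (wildtype replicate 1) to 0.152 (wildtype replicate 2).

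Further genes separated the genotypes on every array without passing the test. Fam96a (current symbol Ciao2a) had a log2 difference of 0.65 (limma adjusted p = 0.0508). Among the other genes of smallest p that were higher, the thrombin receptor gene F2r differed by 0.63, Selp (P-selectin) by 0.63, Gimap4 by 0.84, Arhgap30 by 0.62 and Zfand4 by 0.60. Among those that were lower, Tenc1 (current symbol Tns2) differed by -0.77, Ntf5 by -0.77, Runx1t1 by -0.83, Lst1 by -0.58, the RNA-binding protein gene Igf2bp2 by -1.13, Cdh23 by -0.66, Nrbp2 by -0.85, Fxyd1 by -0.98, Zhx2 by -0.59 and the adaptor gene Dok3 by -0.55. At an adjusted p of 0.1, 24 genes were reached, 12 higher and 12 lower. At an unadjusted p of 0.05, limma counted 1724 genes where chance gives 785.5 on average. Another split of the 8 arrays into 4 and 4 gave 2309, so this count was not beyond what regrouping can give. Of the 1724 genes, 1103, or 64.0%, were higher in elektra. This share was 51.6% after quantile normalization, 82.0% with arrays centred on their medians, 46.1% without the level filter and 73.4% with a stricter filter, so the size of the majority depended on scaling and on the filter, and its direction turned without the filter. The genotypes did not overlap for 984 genes (612 higher and 372 lower), where chance gives 2.86% of genes, or about 449, on average. This count was not taken for the other splits, so it was not shown to exceed what regrouping can give.

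Genes of the dividing cell lay higher in elektra. List means, and values beside a gene name from here on, are log2 differences, elektra minus wildtype. Of 64 genes of DNA replication and S phase, 58 had a higher mean in elektra, with a list mean of 0.23 ± 0.06 (SE, n = 4 and 4; limma camera adjusted p = 5.1e-11, against adjusted p = 0.201 with an estimated correlation). Among its members were Gmnn, which encodes the licensing inhibitor geminin, at 0.53, the uracil glycosylase gene Ung at 0.44, Dtl at 0.41 and the transcription factor gene E2f8 at 0.53. At an unadjusted p of 0.05, 26 of its members were higher and 0 lower, and limma passed 0 members over all genes and 0 adjusted over the list alone. With the interquartile range of the arrays as a covariate, a setting chosen after the ranges were seen, the S phase mean was 0.17 with a standard error of 0.07. The 57 genes of G2 and mitosis averaged 0.26 ± 0.12 (SE; limma camera adjusted p = 8.0e-09, against adjusted p = 0.349 with an estimated correlation). With the array spread as a covariate this mean fell to 0.14 with a standard error of 0.12. Of these genes, 18 were higher and 1 lower at an unadjusted p of 0.05, and 0 passed over all genes. Adjusted over the list alone, 4 passed and all were higher, namely Gas2l3 at 0.85, the cyclin gene Ccnb2 at 0.68, the kinesin gene Cenpe at 0.53 and Gtse1 at 0.57.

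Genes for building ribosomes and charging transfer RNA lay higher as well. The 52 genes of ribosome biogenesis and Myc targets averaged 0.18 ± 0.05 (SE; limma camera adjusted p = 8.5e-09, against adjusted p = 0.201 with an estimated correlation), and 16 were higher and 1 lower at an unadjusted p of 0.05. With the array spread as a covariate the mean fell to 0.12 with a standard error of 0.03. Its members included the nucleolar protein genes Nop58 at 0.38 and Ebna1bp2 at 0.36, Nme1 at 0.38 and the mitochondrial chaperonin gene Hspd1 at 0.40. The 23 aminoacyl-tRNA synthetase genes averaged 0.22 ± 0.06 (SE; limma camera adjusted p = 7.9e-07, against adjusted p = 0.201 with an estimated correlation). With that covariate the mean was 0.18 with a standard error of 0.06. Here 9 members were higher and 0 lower at an unadjusted p of 0.05, among them Lars at 0.62, Mars (current symbol Mars1) at 0.34, Eprs at 0.34 and Gars at 0.34. Only Lars passed among the synthetases adjusted over the list alone and 0 passed in the ribosome biogenesis list, and limma passed 0 of either list over all genes. The 60 genes of cytosolic ribosomal proteins averaged -0.01 ± 0.02 (SE) and did not pass (limma camera adjusted p = 0.239), and their mean turned to 0.04 with arrays centred on their medians, while with the stricter filter they passed as lower (-0.02, adjusted p = 0.0108, range 0.0108 to 0.758 over all settings). None passed adjusted over the list alone or over all genes, with 0 higher and 2 lower at an unadjusted p of 0.05, Rpl10a at -0.31 and Rpl21 at -0.19, while Rpl32 was at -0.27 and Rpl39 at 0.32.

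Genes of respiration and of the interferon response were modestly higher. The 68 genes of oxidative phosphorylation averaged 0.10 ± 0.03 (SE; limma camera adjusted p = 0.000123, against adjusted p = 0.354 with an estimated correlation). With the array spread as a covariate the mean was 0.09 with a standard error of 0.04 and a 95% interval of ± 0.097 that reached 0, and with quantile normalization it was 0.06. Cox5b, a subunit of cytochrome c oxidase, was at 0.38, the complex I subunit genes Ndufs1 and Ndufa1 were at 0.37 and 0.24, and Cycs, which encodes cytochrome c, was at 0.26. Of this list 11 members were higher and 0 lower at an unadjusted p of 0.05, and limma passed 0 over all genes and 0 adjusted over the list alone. The 64 interferon-stimulated genes averaged 0.14 ± 0.04 (SE; limma camera adjusted p = 9.1e-05, against adjusted p = 0.262 with an estimated correlation), with 9 higher and 1 lower at an unadjusted p of 0.05, and with that covariate they averaged 0.13 with a standard error of 0.05 and a 95% interval of ± 0.13 that also reached 0. Ifi27 at 0.59 and Phf11d at 0.88 passed adjusted over the list alone, and 0 passed over all genes. The antiviral gene Oas1a was at 0.33, and Mx2, another antiviral gene, went the other way at -0.33.

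Immediate early genes, which respond within minutes to growth factors and stress, lay lower in elektra. Of 31 tested, 28 had a lower mean, and the list averaged -0.40 ± 0.20 (SE; limma camera adjusted p = 8.0e-09, against adjusted p = 0.284 with an estimated correlation). Nr4a1, which encodes the nuclear receptor Nur77, was at -0.71, the transcription factor genes Egr1 and Junb were at -0.57 and -0.48, and the phosphatase gene Dusp2 was at -0.50. At an unadjusted p of 0.05, 13 members were lower and 1 higher. Only Nr4a1 passed adjusted over the list alone, and 0 passed over all genes. The list means ranged from -0.44 to 0.23 over the elektra arrays and from -0.10 to 0.51 over the wildtype arrays, so the genotypes overlapped (exact permutation p = 0.114). The 17 circadian clock genes averaged -0.10 ± 0.04 (SE; limma camera adjusted p = 0.0260, against adjusted p = 0.201 with an estimated correlation). Its members included the core clock activator gene Arntl at -0.43, Per2 at -0.21 and Per1 at -0.28, with 0 higher and 2 lower at an unadjusted p of 0.05 and 0 passing adjusted over the list alone or over all genes. With arrays centred on their medians the clock mean was -0.06. The clock call was lost without elektra replicate 2 (adjusted p = 0.0525) or wildtype replicate 1 (0.0831), and lowest and highest over all its settings were 0.00388 and 0.201.

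Genes of stem cell identity lay slightly lower, and several genes of multipotent progenitors lay higher. The 58 stem cell identity genes averaged -0.09 ± 0.03 (SE; limma camera adjusted p = 9.6e-05, against adjusted p = 0.201 with an estimated correlation), with 39 lower and 19 higher. The mean moved to -0.04 with arrays centred on their medians and to -0.13 with quantile normalization. At an unadjusted p of 0.05, 10 were lower and 0 higher, among them Art4 at -0.38 and Sult1a1 at -0.34. Adjusted over the list alone, only the lymphotoxin beta gene Ltb passed, at -0.42, and 0 passed over all genes. The 13 multipotent progenitor markers averaged 0.26 ± 0.06 (SE; limma camera adjusted p = 0.0416, against adjusted p = 0.349 with an estimated correlation), with 5 higher and 2 lower at an unadjusted p of 0.05. Plac8 was the member that passed over all genes, and Plac8, the tetraspanin gene Cd53 at 0.92 and the progenitor surface marker gene Cd34 at 0.39 were among those that passed as higher adjusted over the list alone. Mn1, at -0.32, passed as lower adjusted over the list alone and is outside the rule for naming. Without elektra replicate 1, elektra replicate 3, elektra replicate 4, wildtype replicate 1 or wildtype replicate 3 the progenitor list did not pass (adjusted p from 0.0615 to 0.136, in a range over all its settings of 0.00457 to 0.349).

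The 15 stromal and endothelial markers, of cells that the sort is meant to exclude, averaged -0.08 ± 0.08 (SE; limma camera adjusted p = 0.0374, against adjusted p = 0.262 with an estimated correlation), and an exact permutation test on the list means gave p = 0.371. This mean was -0.03 with arrays centred on their medians. Kdr, the receptor gene for vascular endothelial growth factor, was at -0.37, Pdgfrb at -0.33 and Col3a1 at -0.31, while Pecam1 was at 0.23. At an unadjusted p of 0.05, 4 were lower and 1 higher, and 0 passed adjusted over the list alone or over all genes. This call was lost without elektra replicate 1 (adjusted p = 0.111, list mean -0.05), elektra replicate 3 (0.0553, list mean -0.03), wildtype replicate 2 (0.0967) or wildtype replicate 4 (0.0543), and lowest and highest over all its settings were 0.0198 and 0.452.

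**Figure D2:**
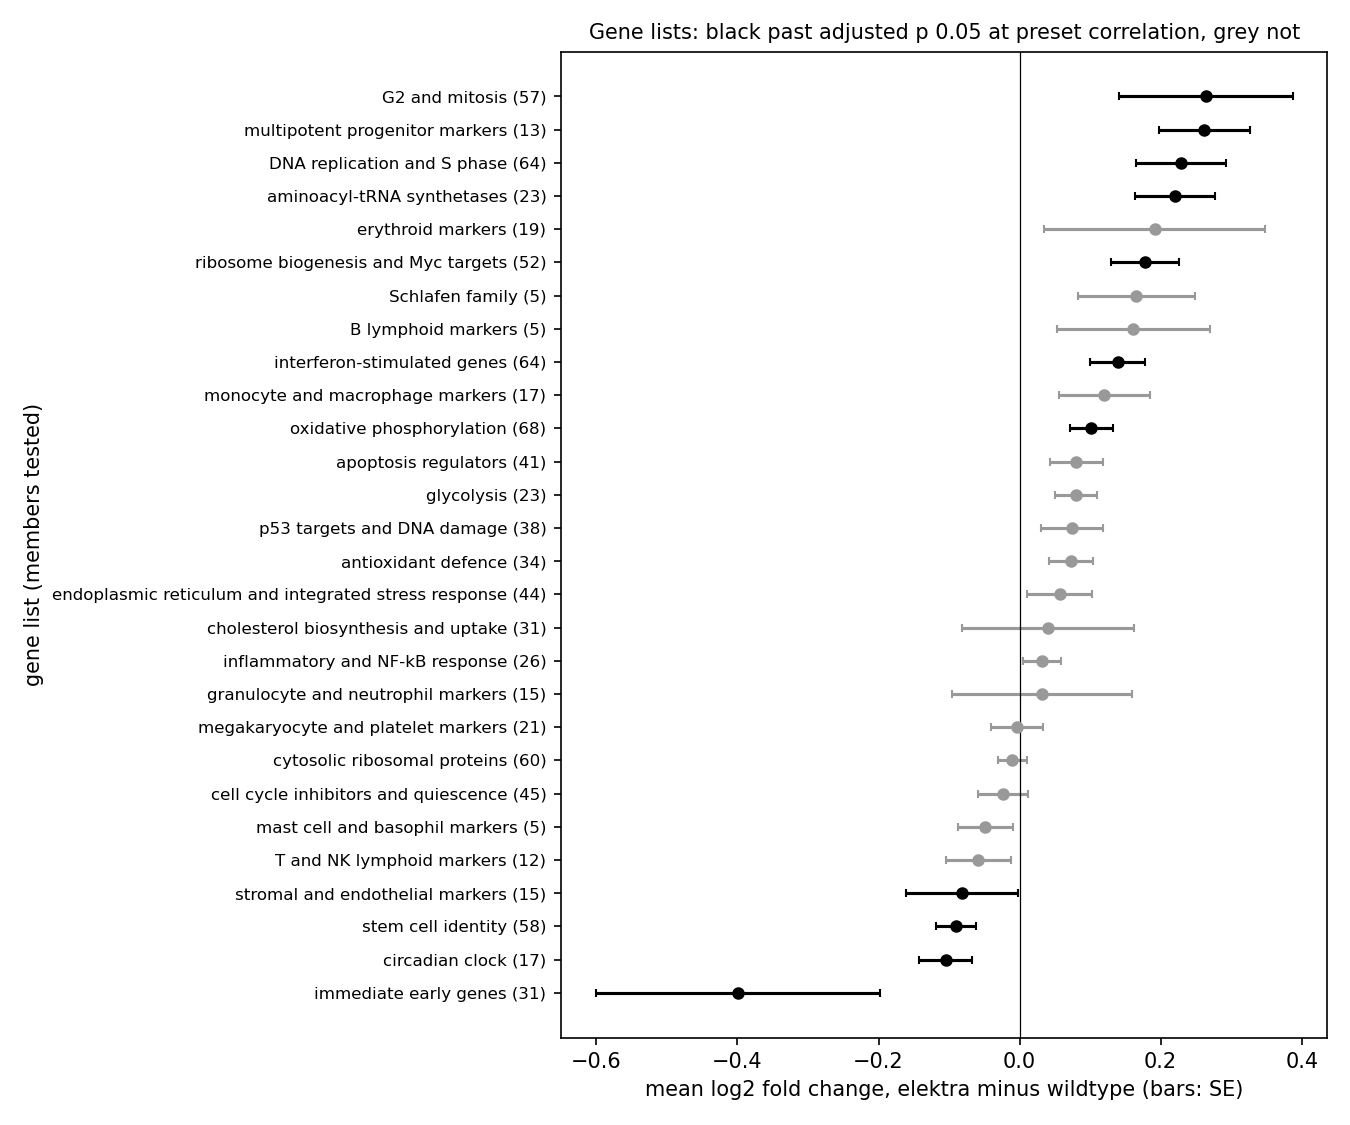
Mean log2 fold change of the tested members of each gene list, elektra minus wildtype (horizontal axis), with bars giving the standard error over arrays and the number of members in parentheses beside each list name (vertical axis). Lists in black passed an adjusted p of 0.05 with limma camera at the preset correlation, the immediate early genes at -0.40 being the lowest and G2 and mitosis at 0.26 the highest.

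Of 28 lists, limma camera passed 11 at the preset correlation, 7 higher and 4 lower. The preset was 0.01, while the correlation estimated from the arrays was 0.16 for S phase and 0.34 for the immediate early genes. With an estimated correlation 0 passed (smallest adjusted p = 0.201), with limma fry 0 passed (smallest adjusted p = 0.0586), and an exact two-sided permutation test of the list means reached its smallest possible p, 0.0286, for 8 lists, 6 higher and 2 lower. After adjustment over the 28 lists that exact test passed 0 (smallest adjusted p = 0.1). The lists at this exact p of 0.0286 were S phase, ribosome biogenesis, synthetases, interferon, oxidative phosphorylation and multipotent progenitors, all higher, and stem cell identity and the circadian clock, both lower, while G2 and mitosis gave p = 0.0857.

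**Figure D3:**
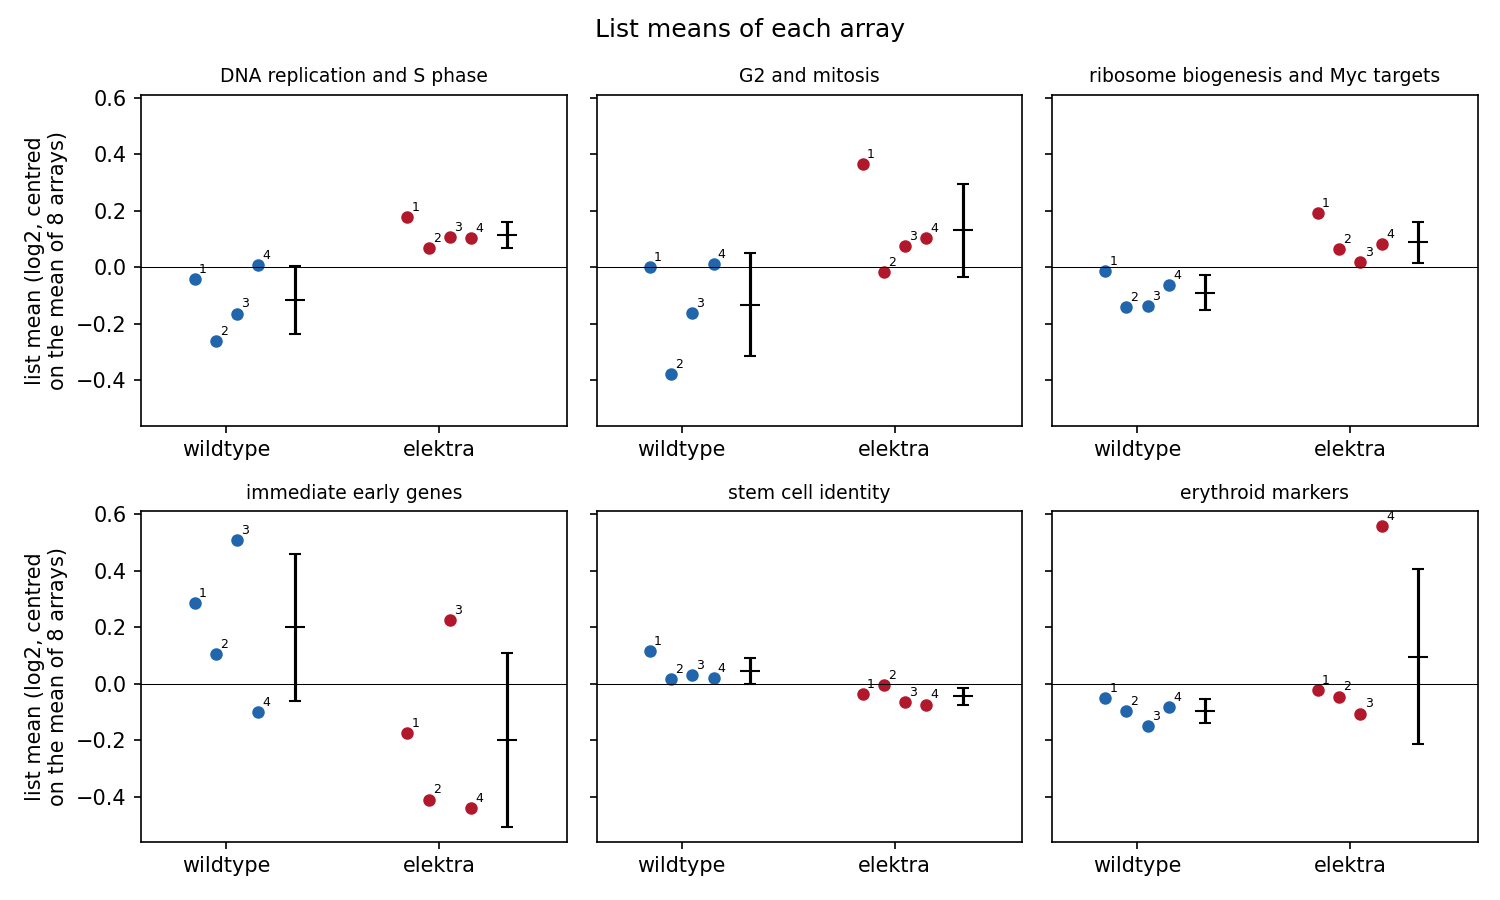
Mean of the members of 6 gene lists on each array (log2, centred on the mean of the 8 arrays, vertical axis), by genotype (horizontal axis), with points numbered by replicate and bars giving the mean and SD of the 4 arrays. The genotypes lie apart for S phase, ribosome biogenesis and stem cell identity and overlap for G2 and mitosis, immediate early genes and erythroid markers, where elektra replicate 4 stands at 0.56.

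Single markers of the megakaryocyte lineage were higher, but the list did not shift. Selp, Pf4, which encodes platelet factor 4, at 0.61 and the integrin gene Itga2b at 0.39 were higher, each adjusted over the list alone, while the list of 21 averaged -0.00 ± 0.04 (SE; limma camera adjusted p = 0.578), turned to 0.04 with arrays centred on their medians and passed 0 over all genes. The 17 monocyte and macrophage markers averaged 0.12 ± 0.06 (SE; limma camera adjusted p = 0.144), and Ctss alone passed, both over all genes and adjusted over the list alone. H2-Ab1 at 0.44 and H2-Aa at 0.37, genes of MHC class II, and Ms4a6c at 0.69 were higher at an unadjusted p of 0.05. This list passed without wildtype replicate 3 (adjusted p = 0.0244), with the stricter filter (0.28, adjusted p = 0.00866) and with the array spread as a covariate (0.16, adjusted p = 0.0477), in a range of 0.00866 to 0.437 over its settings. The 19 erythroid markers averaged 0.19 ± 0.16 (SE; limma camera adjusted p = 0.158) and 0.04 without elektra replicate 4, and passed without the level filter (0.17, adjusted p = 0.00734, range 0.00734 to 0.973 over its settings). Hba-a2, a hemoglobin alpha gene, was at 1.00, Slc4a1 at 0.53, Mt1 at 0.42 and Urod at 0.15, and the list mean of elektra replicate 4 was 0.56 where the other elektra arrays lay from -0.11 to -0.02. Elektra replicate 4 was also highest among the elektra arrays for the 15 granulocyte and neutrophil markers, which averaged 0.03 ± 0.13 (SE; limma camera adjusted p = 0.862) and -0.08 without it, with Ctsg at -0.47, Elane at -0.41, Cxcr2 at 0.28 and Padi4 at 0.23.

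Lymphoid and mast cell markers did not pass as lists, except that the B lymphoid list passed with the array spread as a covariate (0.26, adjusted p = 0.0444, range 0.0444 to 0.878 over its settings). The 12 T and NK markers averaged -0.06 ± 0.05 (SE; limma camera adjusted p = 0.120). Adjusted over the list alone, Nkg7 at 0.57 was higher and Cd247 at -0.33 and Trbc2 at -0.47 were lower, with Cd6 at -0.18. The 5 B lymphoid markers averaged 0.16 ± 0.11 (SE; limma camera adjusted p = 0.229), with Cd72 at 0.29, Cd37 at 0.22, Ighm at 0.41 and Vpreb2 at -0.08, and the 5 mast cell and basophil markers averaged -0.05 ± 0.04 (SE; limma camera adjusted p = 0.584) with a median of 0.01, the opposite sign, from Alox15 at -0.36, Mitf at 0.13, Il6ra at -0.04 and Srgn at 0.02. Srgn turned to -0.0048 with quantile normalization and Il6ra to 0.0065 with arrays centred on their medians.

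Stress and survival genes did not pass as lists either, although 4 of these lists passed as higher without the level filter, p53 targets (adjusted p = 0.00227), apoptosis regulators (0.00734), stress response (0.00360, range 0.00360 to 0.737 over its settings) and antioxidant genes (0.00734, range 0.00734 to 0.386). The 38 genes of p53 targets and DNA damage averaged 0.07 ± 0.04 (SE; limma camera adjusted p = 0.0515), with the proapoptotic gene Bax at 0.27, Psrc1 at 0.36 and Rrm2b at -0.32, and this list passed without elektra replicate 2 (adjusted p = 0.0198), elektra replicate 3 (0.0396) or wildtype replicate 3 (0.0292) and in the 6 arrays of high Xist (list mean 0.11), in a range over its settings of 0.00227 to 0.886. The 41 apoptosis regulators averaged 0.08 ± 0.04 (SE; limma camera adjusted p = 0.0721), with Apaf1 at 0.44 and Dffb at 0.24, and passed without elektra replicate 2 (0.0300) or wildtype replicate 4 (0.0190), in a range of 0.00734 to 0.571. The 44 genes of the endoplasmic reticulum and integrated stress response averaged 0.06 ± 0.05 (SE; limma camera adjusted p = 0.158), and Vldlr alone passed adjusted over the list alone, at 0.56, with Pdia6 at 0.31, Shmt2 at 0.25 and Ern1 at -0.48. The 34 antioxidant genes averaged 0.07 ± 0.03 (SE; limma camera adjusted p = 0.120), and the ferritin light chain gene Ftl1 alone passed adjusted over the list alone, as lower, at -0.39, with Txnrd1 at 0.24, Prdx3 at 0.32 and Taldo1 at 0.22. The 26 genes of inflammation and NF-kB averaged 0.03 ± 0.03 (SE; limma camera adjusted p = 0.862) with a median of -0.00, the opposite sign, from Tnfaip2 at 0.39, Nfkb1 at 0.28, Sod2 at 0.24 and the chemokine gene Ccl4 at -0.36.

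The quiescence and glycolysis lists did not pass, except under 1 filter each, and the cholesterol list passed under no setting (lowest adjusted p = 0.0795). The quiescence list passed as lower with the stricter filter (-0.04, adjusted p = 0.0384, range 0.0384 to 0.919 over its settings), and glycolysis as higher without the level filter (0.08, adjusted p = 0.0238, range 0.0238 to 0.706). The 45 cell cycle inhibitors and quiescence genes averaged -0.02 ± 0.04 (SE; limma camera adjusted p = 0.287), a mean that turned to 0.03 with arrays centred on their medians. Adjusted over the list alone, Nr4a1 was lower and the integrin gene Itgb1, at 0.44, was higher, and Smad3 was at -0.27. The 23 glycolysis genes averaged 0.08 ± 0.03 (SE; limma camera adjusted p = 0.227), with Pgk1 at 0.43, Pfkl at 0.29, Eno2 at -0.30 and Aldoc at -0.21. The 31 genes of cholesterol biosynthesis and uptake averaged 0.04 ± 0.12 (SE; limma camera adjusted p = 0.584), with Hmgcs1 at 0.51, Acat2 at -0.31, Fasn at 0.23 and Ebp at 0.28.

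The deposited table gives its own unadjusted p-values, each equal within 0.0001 to a two-sided equal-variance test on the 4 and 4 log2 values. By those p-values 1583 of the genes tested were under 0.05, 973 higher and 610 lower, of which 1206 were also among the 1724 of limma, and 0 passed after adjustment (smallest adjusted p = 0.133). Slfn2 had the same log2 difference there.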

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

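The tests of array spread for each list and for the Meg3 locus, of progenitor cells in the sort, of the sex of the pools and of the Meg3 locus, the exact p-values of the locus, its microRNA comparison and its parts by level and parent were chosen after the result was seen, and the bounds of the tests of the S phase list, progenitor cells and pool sex were widened after seeing the values from 2 standard errors to 95% intervals, which left the S phase and progenitor tests open. The heat shock test was stated before its result and first run on the genes over the level filter, then on all that it names. Within genotypes, 11 of 310 groups of 4 arrays had an array farther from the rest than Dixon's ratio allows, where chance gives about 5% of groups, or 1 in 20. Of the 35 splits of the arrays into 4 and 4, only the true one gave 6 genes past the adjusted threshold and no other gave any (highest other 0). This is the strongest outcome that 35 splits allow, and it does not by itself exclude chance. At an unadjusted p of 0.05, 2 splits with the true one included reached the real 1724 (highest other 2309). For the lists, 3 splits reached the real 11 (highest other 12), so chance was not excluded for these counts either. Splits with 2 arrays of each genotype on either side, which set no genotype against the other, gave from 0 to 6 lists. Camera at the preset correlation thus called lists also where there was no genotype contrast. The split with 2309 genes set elektra replicates 1, 2 and 4 and wildtype replicate 1, the arrays of largest interquartile range, against the rest, which points to a structure of the arrays beside the genotype. With the interquartile range as a covariate 1244 genes stood at an unadjusted p of 0.05 and 0 past the adjusted threshold. The log2 differences of the 6 called features kept their direction, Plac8 from 1.297 (standard error 0.12) to 1.283 (0.15), Xlr4a from 1.27 (0.17) to 1.10 (0.17), Tjp1 from 0.91 (0.094) to 0.87 (0.11), Ctss from 0.81 (0.099) to 0.87 (0.11), Gm20485 from -0.87 (0.11) to -0.92 (0.13) and Gm24564 from -2.29 (0.31) to -2.02 (0.34). The fit had 1 degree of freedom less, and the errors were larger for all but Xlr4a. The differences were smaller for Xlr4a and Gm24564, and slightly so for Tjp1 and Plac8, and larger for Ctss and Gm20485.

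Growth and cell cycle genes lay higher in elektra stem cells (log2 differences here and in the next patterns), with the S phase list at 0.23 and the G2 and mitosis list at 0.26. With the interquartile range of the arrays as a covariate the S phase mean was 0.17 with a standard error of 0.07 and a 95% interval of ± 0.18 that reached 0 (± 0.16 without it), so array spread and genotype cannot be told apart for this list. The G2 and mitosis mean fell to 0.14, but its interval of ± 0.30 reached 0 without the covariate already, so this test decided nothing for that list. Array spread as the whole cause was argued against for ribosome biogenesis, which fell from 0.18 to 0.12 with an interval of ± 0.087, and for the synthetases, at 0.18 with an interval of ± 0.16. Progenitor cells passing the CD48-negative, CD150-positive gate would raise the transcripts Cd48 and Flt3 and the early granulocyte genes Mpo, Elane, Prtn3 and Ctsg, whose mean was -0.12. They went both ways, Cd48 at 0.14, Flt3 at 0.20, Mpo at -0.18, Elane at -0.41, Prtn3 at -0.0069 and Ctsg at -0.47, with Cd48 and Mpo below the level filter, and the mean was -0.0056 without wildtype replicate 1, where Mpo, Elane and Ctsg read 6.96, 8.45 and 7.29. The mean of -0.12 lay 0.39 below the G2 and mitosis list, but the 95% interval of this difference, ± 0.40, included 0. With each array left out in turn it included 0 too, at 0.31 ± 0.44 without wildtype replicate 1, except without wildtype replicate 3 (0.47 ± 0.43, mean of the 6 genes -0.21), so such cells cannot be told apart from a change within the stem cells. A larger share of stem cells in cycle may also account for the lists, which no measure of cell cycle in these data tests.

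Immediate early genes lay lower in elektra, at -0.40 over the list and -0.71 for Nr4a1. Stress of handling in the wildtype pools was examined through 8 heat shock genes outside the list. The immediate early list itself names the heat shock genes Hspa1a and Hspa1b, which this test therefore left out. The mean of the 8 genes was -0.039 and lay 0.36 above the immediate early list with a standard error of 0.14. They went both ways, with Hsph1 at 0.45, Hsp90ab1 at 0.10, Hspa8 at 0.09 and Dnaja1 at 0.02. Lower were Hspb1, below the level filter, at -0.66, Dnajb1 at -0.20, Hsp90aa1 at -0.11 and Bag3 at -0.01. The mean thus argued only against stress that raises these genes as a set. Stress that raises some of them or leaves heat shock genes as they are was not tested. In the 6 arrays of high Xist the list mean was -0.44 with a standard error of 0.14. This does not decide on the sex of the pools. Low Xist fell on replicate 3 of each genotype, so it was balanced already. Y-linked genes were measured on all 8 arrays, so this subset does not control the share of each sex. The test of array spread decided nothing for this list, since its 95% interval reached 0 without the covariate (± 0.49) and with it (± 0.66), and the mean moved only from -0.40 to -0.35. The time from death to lysis, which no label gives, the sex of the pools and the genotype itself stay open. A lower signalling state of elektra stem cells is therefore a hypothesis only.

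RNAs of the imprinted Meg3 locus lay lower in elektra beyond the feature Gm24564, which passed in 7 of 20 settings, with Meg3 at -0.83 and the small RNA feature AF357425 at -2.55, neither of which passed adjustment, and Rian at -1.13, which lay below the level filter, as did 44 of the 61 features of the locus. The locus holds noncoding RNAs expressed from the maternal chromosome and the paternal genes Dlk1, at -0.35, and Rtl1, at -0.010. A fault of single features was argued against by the other 57 features of the locus, whose mean was -0.26 with 51 below 0, outside the middle 95% of random lists of like level (-0.097 to -0.0027) and at the smallest exact p of 0.0286. Without Dlk1 and Rtl1 the mean was -0.26, and the 13 features of these over the level filter averaged -0.23 with 13 below 0 (random lists -0.11 to 0.090, exact p = 0.0571). A shift of all microRNA features was argued against too, since the 43 in the locus averaged -0.26 and the 483 outside it -0.05. Array spread was argued against by Meg3 at -0.72 (standard error 0.18) with the interquartile range as a covariate, where Rian was at -1.12 (standard error 0.25). Lower expression of RNAs of this locus in the elektra samples may therefore be biological, which is a hypothesis found and tested on the same 8 arrays. Differences between the pooled mice other than genotype were not tested. Neither was a different share of progenitor cells in the sort tested for this locus.

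The remaining arrays that stood apart are given as values, list means in log2 centred on the 8 arrays and genes as log2 signals. The mean of the stem cell identity genes was 0.12 on wildtype replicate 1 and 0.02 to 0.03 on the other wildtype arrays. The mean of the apoptosis regulators was 0.12 on elektra replicate 1 and 0.01 to 0.02 on the other elektra arrays. The mean of the erythroid markers was 0.56 on elektra replicate 4 and -0.11 to -0.02 on the other elektra arrays. The mean of the granulocyte and neutrophil markers was 0.36 on elektra replicate 4 and -0.14 to -0.06 on the other elektra arrays. The mean of the mast cell and basophil markers was -0.082 on wildtype replicate 1 and 0.05 to 0.07 on the other wildtype arrays. Fam96a was at 9.40 on elektra replicate 4 and 9.58 to 9.60 on the other elektra arrays. Gtse1 was at 7.09 on wildtype replicate 4 and 6.96 to 6.98 on the other wildtype arrays. Eprs was at 8.97 on wildtype replicate 2 and 9.29 to 9.33 on the other wildtype arrays. Elane was at 8.45 on wildtype replicate 1 and 6.73 to 6.91 on the other wildtype arrays. Xist was at 5.06 on elektra replicate 3 and at 5.37 on wildtype replicate 3, and at 10.26 to 10.79 on the others of both genotypes.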

How the results depend on the processing

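The settings of Xist level, of array spread and of the deposited p-values were chosen after the data were seen. The S phase, G2 and mitosis, ribosome biogenesis, synthetase, interferon, oxidative phosphorylation, stem cell identity and immediate early lists kept their direction and passed in all 20 settings that kept limma camera at the preset correlation, from 0.17 to 0.28, 0.14 to 0.31, 0.12 to 0.23, 0.17 to 0.27, 0.10 to 0.19, 0.06 to 0.15, -0.13 to -0.04 and -0.54 to -0.30, respectively. The cause of the changes that follow was not tested, except that fewer arrays, a block or a covariate leave fewer degrees of freedom and that the filters change the genes tested. Signal near background limits the rest, since Slfn3, Slfn4, Slfn10-ps and Slfn14 lay below the level filter.

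With an estimated correlation, with fry and with the exact permutation of list means, 0 lists passed while the means are the same by construction, S phase 0.23, G2 and mitosis 0.26, stem cell identity -0.090, interferon 0.14, synthetases 0.22, ribosome biogenesis 0.18, oxidative phosphorylation 0.10, immediate early -0.40, circadian -0.10, multipotent progenitors 0.26 and stromal -0.081. The genes past the adjusted threshold were 6, and 3 with no filter on the level, 13 with the stricter filter, 3 with array median centring, 18 with trend and robust, 24 at adjusted p under 0.1, 2 in the 6 arrays with high Xist, 0 with array spread as a covariate (1244 at an unadjusted p of 0.05), 0 by the authors' deposited p after adjustment (1583 unadjusted) and 0 with the replicate block (1848 unadjusted). Whether replicate numbers pair the arrays was not settled. After removing genotype means the correlation within a number was 0.14, 0.02, 0.13 and -0.00, and 4 of 8 arrays correlated best with their own number. Low Xist fell on replicate 3 of both genotypes. With the replicate block Plac8 stood at a limma adjusted p of 0.0826. Genes at an unadjusted p of 0.05 were 2686 with no filter and 1141 with the stricter filter, against 1724.

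The circadian list did not pass with no filter (-0.11). The multipotent progenitor list did not pass with the stricter filter (0.27), quantile normalization (0.24), the mean of all features (0.23) or the 6 arrays with high Xist (0.23). The stromal list did not pass with no filter (-0.050), quantile normalization (-0.085), the 6 arrays with high Xist (-0.017) or array spread as a covariate (-0.10). With the stricter filter Tjp1 and other dim genes were not tested, and the stromal, Schlafen, granulocyte, B lymphoid, T and NK and mast cell lists had too few members left for a value, as the B lymphoid list had with the mean of all features. Directions turned for ribosomal proteins with no filter (0.0039), array median centring (0.038) and the 6 arrays with high Xist (0.0037), for mast cells with no filter (0.030), for quiescence (0.025) and megakaryocytes (0.045) with array median centring, and for cholesterol (-0.040), granulocytes (-0.037) and T and NK markers (0.0071) with array spread as a covariate, none of which passed. Srgn turned to -0.0048 with quantile normalization, Il6ra to 0.0065 with array median centring, Slfn1 to -0.050 in the 6 arrays with high Xist and Vpreb2 to 0.20 with array spread as a covariate.

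With each array left out in turn, genes past the adjusted threshold ranged from 0 (elektra replicate 4) to 4 and unadjusted ones from 1245 to 2137, lists from 9 to 12 and Slfn2 from 0.18 to 0.58. The list means ranged from -0.13 to -0.078 for circadian, 0.23 to 0.32 for multipotent progenitors, -0.14 to -0.030 for stromal, -0.041 to 0.12 for cholesterol, -0.034 to 0.020 for megakaryocytes, -0.082 to 0.085 for granulocytes, -0.045 to 0.0031 for quiescence and -0.020 to 0.0042 for ribosomal proteins. Slfnl1 ranged from -0.00091 to 0.076, Slfn1 from -0.035 to 0.091, Il6ra from -0.081 to 0.012 and Vpreb2 from -0.21 to 0.036. Over all settings, named genes kept direction and side of the threshold in 2383 results, lost the threshold in 61, gained it in 25 and turned in 9. Lists that did not pass gained a call in 19 results, 7 of them higher with no filter.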

Other observations

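The test of imprinted genes outside the Meg3 locus was stated before its result was seen, and its exact p-values, its parts by level, the choice of Y-linked values and the features outside the gene test were looked at after. Several imprinted genes, a class that includes regulators of growth, had lower means in elektra. The log2 difference, elektra minus wildtype, of H19 was -0.59, Plagl1 at -0.41, Ascl2 at -0.34, Igf2 at -0.33, Snrpn at -0.28 and Ndn at -0.28, and Dlk1, the protein-coding gene beside Meg3 that is expressed from the paternal chromosome, was at -0.35. H19, Plagl1 and Ascl2 lay below the level filter and outside the gene test, and the others did not pass adjustment. An imprinted gene network, in which such genes change together, is a candidate explanation, and the mean of 28 measured imprinted genes outside the locus was -0.12, with 20 below 0. That lay below the middle 95% of random lists of like level (-0.09 to 0.05, percentile 0.61), but an exact permutation test over the arrays gave p = 0.0857, so the shift was not established against the spread between arrays. The 15 over the level filter averaged -0.11 (exact p = 0.0286, the smallest possible) and the 13 below it -0.12 (exact p = 0.143). Igf2r at 0.06, Phlda2 at 0.11 and, below the level filter, Asb4 at 0.23 went the other way.

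Genes of antigen presentation by MHC class II, chosen after their values were seen, were measured well above the level filter in both genotypes. H2-Ab1 was at 10.50 ± 0.23 (SD, n = 4) in elektra and 0.44 higher than in wildtype, H2-Aa at 9.38 ± 0.27 and 0.37 higher, H2-Eb1 at 8.68 ± 0.28 and 0.18 higher, and Cd74, which encodes the invariant chain, at 9.54 ± 0.28 and 0.31 higher. None of them passed over all genes. Ctss, which cleaves the invariant chain, was the gene of this group that did.

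Y-linked genes were measured on all 8 arrays, Ddx3y from 7.77 to 8.66 (log2 signal), Eif2s3y from 7.76 to 9.10, Uty from 7.15 to 8.31 and Kdm5d from 6.94 to 7.60, while Usp9y lay from 3.92 to 4.13. Xist was high on 6 of these arrays.

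Features of the series table alone and those with no symbol or several symbols gave 0 past the adjusted threshold with limma. Genes left out by the level filter were not in these sets. With no filter on the level 3 genes passed, of which 2 also passed with the filter. Of the 7552 of the series table alone, 429 stood at an unadjusted p of 0.05, where chance gives 377.6. Of the 1591 with no symbol 99 did, and of the 128 with several symbols 9 did.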
